A study of Arabidopsis thaliana with 8 samples.

How the data were processed

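Total RNA from whole Arabidopsis thaliana plants was measured on 8 custom Agilent arrays of 1 colour (Cy3), 1 array per sample. Per the labels' protocols, plants of 2 weeks grown in liquid medium under continuous light were moved to fresh medium with 15 µM zeocin or without it for 2 h, and the replicates are biological. The groups were taken from the sample titles: WT mock, WT zeocin, sog1-1 mock and sog1-1 zeocin, with 2 arrays each. Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09 on design 034592, and the processed intensity is a background-subtracted and spatially detrended brightness on a linear scale. Other columns hold marks per spot, per the file headers, for signal well above background, saturation and outliers. The submitters' processing notes name RMA and limma, with no version and no role. The deposited table of processed values was read as log2 values, because across features each of its columns had a correlation between 0.988 and 0.990 with the log2 scanner values of the array of the same sample. Its column medians were 4.93, 4.95, 4.96 and 4.95 in WT mock 1 and 2 and WT zeocin 1 and 2, and 4.95, 4.95, 4.93 and 4.96 in sog1-1 mock 1 and 2 and sog1-1 zeocin 1 and 2. How that deposited table was background-corrected and scaled is not given in the sources used here, and it served as an alternative.

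Values were log2 of the processed intensity minus the 75th percentile of each array over its 53459 non-control features. Control features (1319) and spots marked as outliers (24 to 40 per array) were left out, and no spot was saturated. Spots of the same probe were averaged. Of 52586 probes, 32781 carry a locus name, with 1 probe per locus, so no choice among probes of a gene was needed. Symbols come from the RefSeq table of assembly TAIR10.1, which held 32316 of those 32781 loci and 22169 of the 22255 tested. A gene is named by its locus otherwise. The files name no genome build, so no coordinates are given, and position along a chromosome means the order of the locus numbers. The other 19805 probes, whose names give no locus, were tested apart.

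A locus was tested when its probe was well above background on both arrays of at least 1 group, which left 22255 genes, 21005 of them above background on all 8 arrays. Means of the 4 groups were fitted to all 8 arrays with lmFit and moderated with eBayes in limma 3.58.1 under R 4.3.3, with 4 residual and 2.01 prior degrees of freedom. The contrasts were zeocin against mock in WT, zeocin against mock in sog1-1, the difference of these responses (WT minus sog1-1), and sog1-1 against WT without zeocin. P values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p below 0.05. Every adjusted p of a gene is limma's, and errors of log2 changes are standard errors of this fit. With 2 arrays per group the number of arrays limits the precision. The 95% interval of a change with zeocin in sog1-1 reached a median of 0.31 to either side.

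A probe not well above background on both arrays of a group has only a bound there. Its fold is then given as "at least", from the brighter group's mean and, for the dimmer group, the mean over arrays of the higher of the probe's own value and the lowest value of any probe well above background. No fold is given where both groups were below.

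The 18 gene lists (289 loci, 16 of them in more than 1 list) were compiled from general knowledge before the data were examined, as were the contrasts, the alternatives and the rule for named genes. They cover DNA repair, damage sensing, known damage response genes, cyclin-dependent kinase (CDK) inhibitors, G2 and M phase, DNA replication, jasmonate, salicylate, oxidative stress, heat shock, touch, clock, developmental cell death, iron, copper, and markers of shoot and root. It is not known whether the reports behind the list of known damage response genes used these same samples. Neither its rise nor its difference between genotypes is therefore independent evidence. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. The estimated form also uses the 4 residual degrees of freedom in place of the number of genes. A call lost there therefore need not reflect correlated genes. Adjustment was over the 18 lists within a contrast, and 12 genes with a missing value were left out. Camera compares a list with the other genes, and fry tests whether its members move at all, on balance one way or, in its mixed form, in either direction.

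Genes named are SOG1, the 10 largest rises and falls with zeocin in WT, the 5 largest in each other contrast among called genes whose arrays did not overlap between groups, and up to 4 called members of each list. For the difference, the WT arrays had to not overlap between treatments. Where no member of a list passed, the 1 member with the largest change could be named. Not every gene that the rule names is reported here. AT4G19760 falls outside the rule and was chosen after its values were seen.

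Values were simulated for 22243 genes with independent noise at each gene's moderated spread, the same in all groups. Of genes changed by log2 0.5, 1, 2 and 4, 2, 72, 94 and 100% were called for zeocin in WT, and 12, 64, 88 and 100% for zeocin in sog1-1, with 50 genes per size. The real groups differed in spread and genes were correlated, so these rates are approximate. Unchanged genes made up 8 of 142 and 4 of 136 calls.

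All arrays lay on 1 slide with 1 scan. WT arrays filled one row and sog1-1 arrays the other, in the order of the groups, so row and genotype cannot be told apart, nor column and treatment. An additive effect of the row cancels in the difference of responses. The alternatives were quantile normalization, normexp background correction (offset 50) with either scaling, the deposited values, other filters on dim probes, eBayes with trend and robust, a fit of only the groups compared, the replicate number as a block, other thresholds, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.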

Results

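The series measured how a DNA-damaging drug changes gene expression in Arabidopsis with and without SOG1 (AT1G25580), a NAC transcription factor of the plant DNA damage response. Zeocin is a bleomycin-type antibiotic that cuts both DNA strands. The Col-0 wild type (WT) and the mutant sog1-1 were treated for 2 h with 15 µM zeocin or mock medium, with 2 arrays in each of the 4 groups. Between 28210 and 29573 of the 53459 non-control features per array (52.8 to 55.3%) were well above background, and the 75th percentile of the processed intensity lay between 443 and 520. Across genes, the arrays of a replicate pair correlated at 0.987 to 0.994, arrays of the same genotype under the other treatment at 0.980 to 0.994, and arrays of different genotype at 0.939 to 0.979. These correlations are across genes, which are not independent replicates. The median SD between replicates (log2) was 0.085 in WT mock, 0.126 in WT zeocin, 0.087 in sog1-1 mock and 0.094 in sog1-1 zeocin.

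The SOG1 transcript was measured on every array. Its normalized log2 level was 1.08 ± 0.02 (SD, n = 2) in WT mock, 1.09 ± 0.04 in WT zeocin, 1.05 ± 0.08 in sog1-1 mock and 1.21 ± 0.05 in sog1-1 zeocin. No contrast of it passed the test (limma, adjusted p = 0.862 for genotype and 0.997 for zeocin in WT). The transcript level therefore does not separate the genotypes and checks the labels no further.

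The comparison of zeocin with mock in WT asked which genes respond to the damage. The genes that rose included ones known from DNA repair, CDK inhibition and nucleotide supply. SMR7 (AT3G27630), a CDK inhibitor of the SIAMESE-RELATED family, rose by log2 7.53 ± 0.28 (SE, n = 2 per group, adjusted p = 0.000145), and the thymidine kinase gene TK1A (AT3G07800) rose by 6.30 ± 0.09 (adjusted p = 1.21e-05). The homologous recombination gene BRCA1 (AT4G21070) rose by 5.58 ± 0.14, and XRI1 (AT5G48720), named for its induction by X-rays, by 5.31 ± 0.11. In all 303 genes were higher and 14 lower among the 22255 tested, of which 221 rose and 4 fell by log2 1 or more. Of the 221, 35 were not well above background in WT mock. Their median change was 2.25 as fitted and 2.04 with those 35 at their bound.

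Other genes among the 10 largest rises belong to several functions. AT4G25330 was not well above background on either WT mock array and rose at least 60.1-fold (fitted log2 8.13 ± 0.15). AT5G07610, measured on every WT array, rose by 8.65 ± 0.94 (adjusted p = 0.0109), and its call ended without any 1 of the 4 WT arrays. KCS17 (AT4G34510), a synthase of very-long-chain fatty acids, changed by 6.55 ± 0.56, with 1 of 2 WT mock arrays well above background. GEX1 (AT5G55490), a gene known from gametes, rose by 6.15 ± 0.16 and AT2G18193 by 5.95 ± 0.16.

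All 16 tested members of the list of known damage response genes rose, with a median of 4.36, and all 16 rose when adjusted over the list alone. This list stood apart from other genes at an adjusted p of 1.13e-67 by camera, and it was the only list whose call held with an estimated correlation (adjusted p = 0.00557). Part of the list may rest on reports that used these samples, so this is not independent evidence of its direction. Among homologous recombination genes (median 0.35), 8 of 22 rose and 0 fell, or 10 and 1 adjusted over the list alone. COM1 (AT3G52115), needed for the trimming of DNA ends, rose by 4.49 ± 0.13, and SYN2 (AT5G40840), a cohesin subunit, by 4.27 ± 0.35 with 1 of 2 WT mock arrays well above background. The list had an adjusted p of 1.8e-16 by camera and an adjusted p = 0.0820 with an estimated correlation. Of 8 genes of end joining and poly(ADP-ribose) polymerases, 2 rose, also when adjusted over the list alone, namely PARP2 (AT4G02390, 4.73 ± 0.15) and PARP1 (AT2G31320, 3.24 ± 0.13). Of 18 genes of damage sensing, checkpoint and transcription factors, 3 rose (4 adjusted over the list alone): the checkpoint clamp loader RAD17 (AT5G66130) by 3.42 ± 0.13, the NAC factor gene ANAC044 (AT3G01600) by 2.55 ± 0.09 and the kinase gene WEE1 (AT1G02970) by 1.32 ± 0.09. The medians of these lists were 0.12 and 0.05. For both the adjusted p was 0.000164 by camera and the adjusted p = 0.0810 with an estimated correlation. Their estimated correlations, -0.04 and -0.02, lay below the preset 0.01, so correlation among the genes does not account for the weaker p.

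Of 21 CDK inhibitor genes 6 rose, with SMR5 (AT1G07500) at 5.23 ± 0.20, SMR4 (AT5G02220) at 3.90 ± 0.24 and KRP6 (AT3G19150) at 1.52 ± 0.14 after SMR7. Adjusted over the list alone, 7 were higher and 2 lower. The median of the list was -0.03 and its mean 0.91, with the direction Up by camera (adjusted p = 0.000837, and adjusted p = 0.299 with an estimated correlation). Of 32 genes of G2 and M phase, 1 rose, the cyclin gene CYCB1;1 (AT4G37490) at 4.22 ± 0.12, while the median of the list was -0.25 with the direction Down (camera adjusted p = 0.000164, and adjusted p = 0.639 with an estimated correlation). Adjusted over the list alone, 1 was higher and 1 lower. Of 20 genes of DNA replication and nucleotide supply 3 rose, all of nucleotide supply: TK1A and the ribonucleotide reductase genes TSO2 (AT3G27060, 4.45 ± 0.11) and RNR1 (AT2G21790, 1.40 ± 0.10). Adjusted over the list alone, 3 were higher and 5 lower. The median of this list was -0.29, its mean 0.36 and its direction Down, and camera did not call it (adjusted p = 0.0692). It was called lower with quantile normalization (adjusted p = 0.0459) and with normexp and quantile (adjusted p = 0.0486), while fry gave the opposite direction, Up (adjusted p = 0.00694).

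Stress lists held few called genes. The kinase gene OXI1 (AT3G25250, 4.86 ± 0.37) and UPOX, a mitochondrial protein gene induced by oxidants, (AT2G21640, 1.33 ± 0.13) rose among 19 genes of oxidative stress, with 3 higher adjusted over the list alone. WRKY50 (AT5G26170, 3.31 ± 0.36) and WRKY25 (AT2G30250, 1.52 ± 0.18) rose among 21 genes of salicylate and pattern-triggered defence, with 3 higher adjusted over the list alone. The medians were 0.14 and 0.22. The calls of UPOX and WRKY50 ended without either WT mock array, that of UPOX also without WT zeocin array 2 and that of WRKY50 without WT zeocin array 1. That of WRKY25 ended without any 1 of the 4 WT arrays or either sog1-1 zeocin array. Camera adjusted p values were 0.00346 and 0.00361, with adjusted p = 0.629 and adjusted p = 0.639 with an estimated correlation. Relative to each gene's mean over all arrays, the defence list had medians of 0.32 and -0.59 on the WT zeocin arrays 1 and 2, and the jasmonate list 0.02 and -0.81, so the replicates of this group differed in both. In the other groups array 1 also lay above array 2, with -0.23 and -0.65 for defence in WT mock. The median of the defence list was -0.43 without WT zeocin array 1, and that of the jasmonate list 0.20 without WT zeocin array 2, each the reverse of its direction with all arrays. Each of these fits sets 1 zeocin array against both WT mock arrays. No gene of the lists of heat shock, touch, jasmonate, clock, developmental cell death, iron, copper, shoot or root markers was called, also when adjusted over the list alone. Their medians were 0.19, 0.33, -0.21, -0.02, -0.24, -0.04, -0.10, -0.13 and -0.12. Camera called heat shock (adjusted p = 0.0251) and touch (adjusted p = 0.0312) higher, each with an adjusted p = 0.639 with an estimated correlation, and both calls ended with the deposited values. By fry, 6 of the 18 lists moved one way in WT and 9 passed its mixed form. For the clock and iron lists the median and mean were below 0 and the camera direction was Up, without a call.

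The 10 largest falls were smaller than the rises. LBD14 (AT2G31310), a LOB-domain factor gene, fell by 1.48 (SE 0.17, adjusted p = 0.0160), and AT2G37960 and AT3G56260 had changes of -1.11 and -1.1. AT5G59670, AT5G20670, AT4G15830, ASL5, AT3G33080 and PAP16 had changes of -0.84, -0.81, -0.70, -0.70, -0.68 and -0.67. AT1G19060 had a fitted change of -1.48 but was not well above background on any WT array. The calls of all 10 falls ended when either WT mock array was left out, and each also ended without WT zeocin array 1. AT3G33080, AT3G56260, AT4G15830 and PAP16 lost the call without any 1 array and with the deposited values. The count of rises was 163 or 151 without WT mock array 1 or 2, 191 or 163 without WT zeocin array 1 or 2, and 143 when only the WT arrays were fitted.

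**Figure D1:**
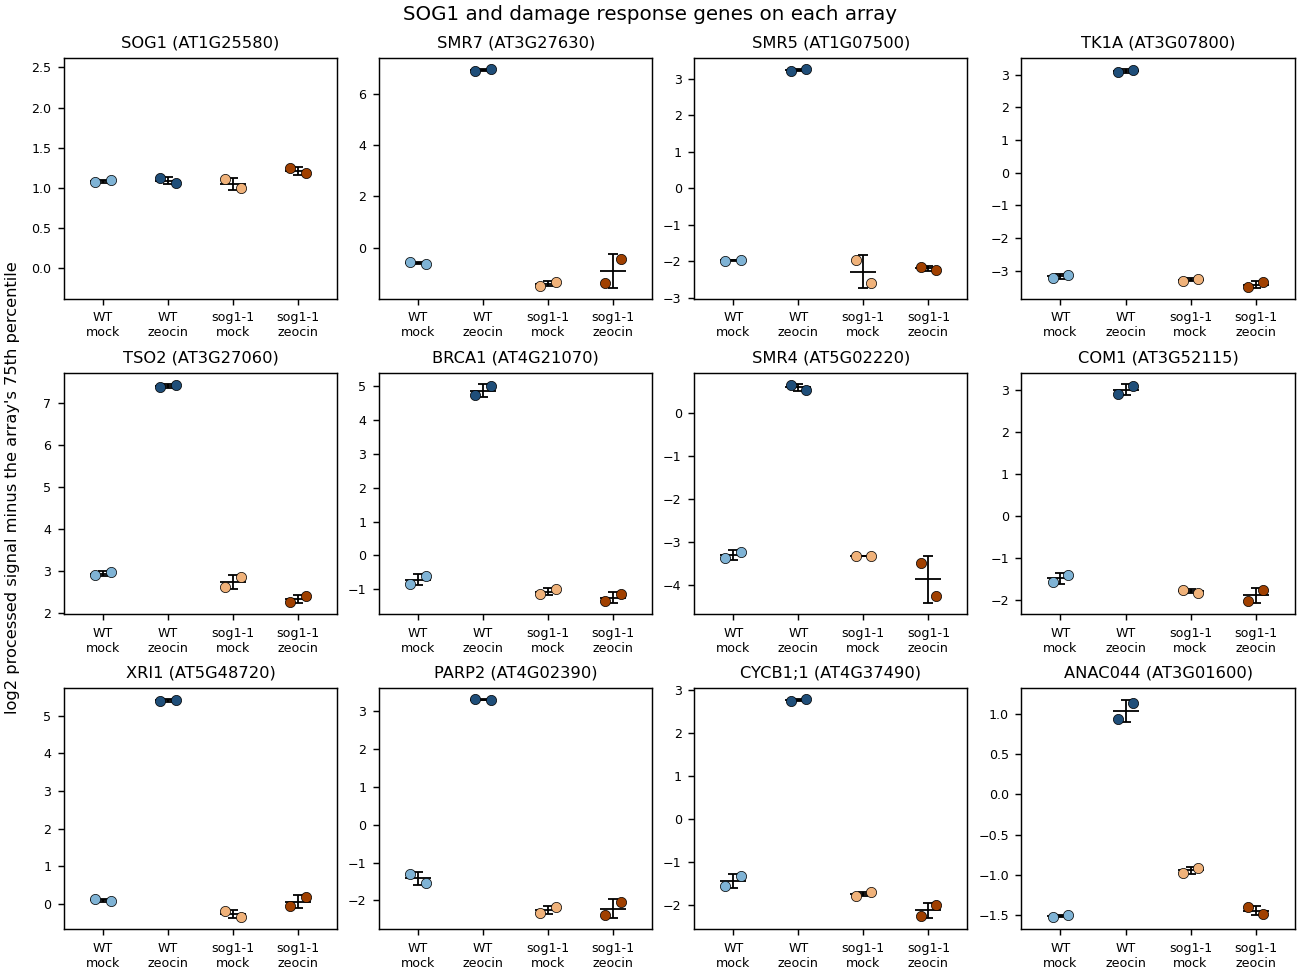
Normalized log2 signal (vertical axis, processed intensity relative to the array's 75th percentile) of SOG1 and 11 damage response genes on each of the 8 arrays (points), with the group mean (bar) and SD (whiskers). SMR7 had a mean of 6.93 in WT zeocin and of -0.59, -1.41 and -0.90 in WT mock, sog1-1 mock and sog1-1 zeocin, and the group means of SOG1 lay between 1.05 and 1.21.

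The same treatment in sog1-1 asked how much of this response remains in the mutant. No gene was called higher or lower for zeocin in sog1-1 (limma), while 1742 had an unadjusted p below 0.05 and chance gives 1113. The count was 0 under each of the 5 ways of computing the values. The damage response genes named above had no called change, among them BRCA1 -0.18 ± 0.14, TK1A -0.15 ± 0.09, PARP2 0.05 ± 0.15, SMR7 0.51 ± 0.28, ANAC044 -0.50 ± 0.09 and WEE1 -0.48 ± 0.09. Of these, ANAC044 and WEE1 had the changes largest relative to their standard errors. Over the 221 genes raised by log2 1 or more in WT, the median change in sog1-1 was -0.0028, with 90% of genes between -0.54 and 0.81, and 110 were above 0. The median was 0.04 over those measured in at least 1 sog1-1 group, with 30 genes not well above background in either. The largest of these changes was 2.06. Across all genes the changes in WT and sog1-1 correlated at 0.0355, and across the 221 genes at 0.179. In sog1-1, AT5G07610 was well above background on 1 of 2 zeocin arrays and 0 of 2 mock arrays, so its fitted change of 1.97 ± 0.94 (adjusted p = 0.587) gives no size. GEX1 was so on 2 of 2 zeocin and 0 of 2 mock arrays, at least 1.38-fold higher with zeocin (adjusted p = 0.587).

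By list, the known damage response genes had a median of -0.11 in sog1-1 with 0 of 16 called (0 higher and 1 lower adjusted over the list alone), and SYN2 had the largest change, -0.53 ± 0.35. Camera called 9 lists, 3 higher and 6 lower, and every one had an adjusted p = 0.556 with an estimated correlation. The lists called higher were salicylate defence (median 0.61, adjusted p = 3.87e-07), jasmonate (0.39, adjusted p = 0.000127) and touch (0.55, adjusted p = 0.0119). Those called lower were G2 and M phase (-0.24, adjusted p = 2.78e-06), DNA replication (-0.18, adjusted p = 4e-06), heat shock (-0.56, adjusted p = 0.0119), shoot markers (-0.28, adjusted p = 0.0119), homologous recombination (-0.15, adjusted p = 0.0337) and CDK inhibitors (-0.08, adjusted p = 0.0358). The calls of homologous recombination and CDK inhibitors ended with quantile normalization, with normexp and quantile, with the deposited values and without the filter on dim probes. The members with the largest changes, none of them called, were FRK1 (1.55 ± 0.65), JAZ8 (0.84 ± 0.59), CYCA2;1 (-1.82 ± 0.81), FAS1 (-0.77 ± 0.32), HSP17.6II (-1.07 ± 0.67) and SMR13 (-0.57 ± 0.19) in the defence, jasmonate, G2 and M phase, replication, heat shock and CDK inhibitor lists. Relative to the gene means, the heat shock list had medians of 0.66 and -0.19 on sog1-1 zeocin arrays 1 and 2 and of 1.29 and 0.01 on sog1-1 mock arrays 1 and 2. Medians of the damage sensing, end joining, oxidative stress, clock, cell death, iron, copper and root lists were -0.02, -0.02, 0.28, -0.11, -0.01, 0.10, -0.09 and -0.02, without a camera call. Adjusted over the list alone, 3 damage sensing genes and 1 G2 and M phase gene were lower and no other gene was called. For the cell death and root lists, the mean was above 0 and the median below 0. By fry, no list moved one way (smallest adjusted p = 0.365), and 2 lists passed its mixed form, known damage response genes (adjusted p = 0.00531) and damage sensing (adjusted p = 0.0218).

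**Figure D2:**
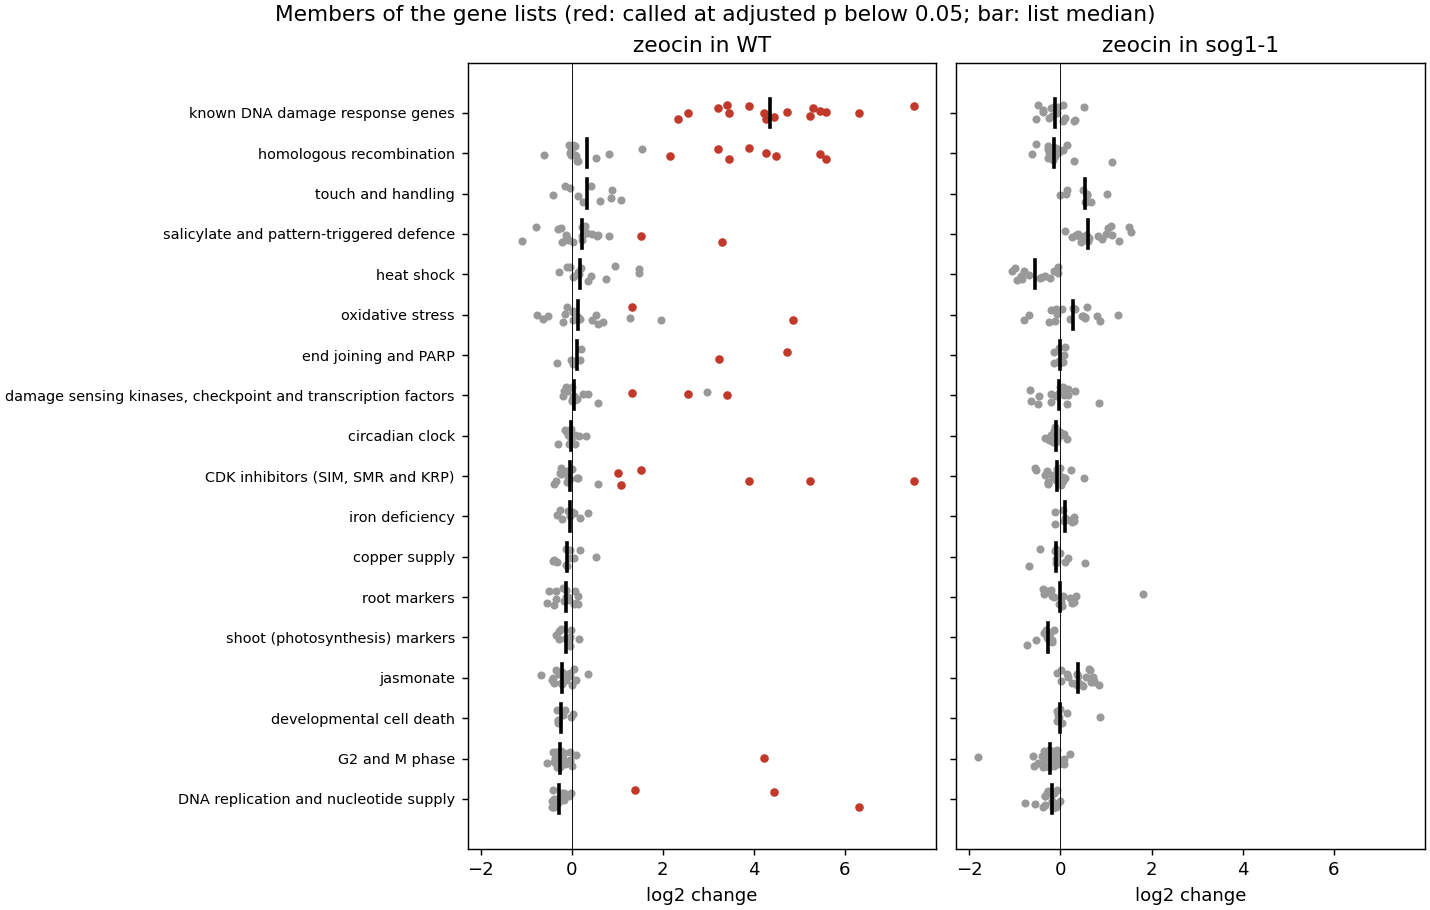
Log2 change with zeocin of each tested gene of the 18 lists (points) in WT (left) and sog1-1 (right), with the list median as a bar and genes called at an adjusted p below 0.05 in red. In WT the 16 known damage response genes had a median of 4.36, and in sog1-1 a median of -0.11 with 0 called.

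The direct test of whether the responses differ is the WT change minus the sog1-1 change. It was called higher for 165 genes and lower for 5. Of the 221 genes raised by log2 1 or more in WT, 139 (62.9%) were called higher in this difference, and they are referred to as SOG1-dependent raised genes. The label names this test result and does not show that SOG1 itself is the cause. Of the 4 genes lowered by log2 1 or more in WT, 0 were called lower in the difference. One of the 4, AT1G19060, was not well above background on any WT array, so so few genes say little about lowering. The 139 had a median change of 2.55 in WT (2.34 with 18 genes at their bound) and -0.08 in sog1-1. The contrasts share the WT arrays. In 100 simulations without effects these contrasts correlated across genes at a median of 0.705, and the calls they shared had a median of 0 and a maximum of 1, a value that leaves out real effects. Independent lists of these sizes would share 1.64 genes, a value that leaves out the shared arrays. Part of the excess may come from the shared arrays, since groups of 2 arrays cannot be split. Another 139 genes raised in WT were not called in the difference, with median changes of 1.1 in WT and 0.12 in sog1-1.

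Among the genes named for the size of their fitted difference, SMR7 (7.02 ± 0.40, adjusted p = 0.00134) and TK1A (6.45 ± 0.13, adjusted p = 8.43e-05) were well above background on every array. KCS17 (6.88 ± 0.79, adjusted p = 0.0251) and AT4G05380 (5.87 ± 0.39, adjusted p = 0.00255) were so on 1 of 2 arrays in each group but WT zeocin. AT4G25330 (8.21 ± 0.22, adjusted p = 0.000248) was below background in every group but WT zeocin, so its fitted difference gives no rank, and its rise in WT was at least 60.1-fold. In the group of known damage response genes, 16 of 16 were called, with a median difference of 4.75 (16 also adjusted over the list alone, camera adjusted p = 5.66e-58, and adjusted p = 0.00757 with an estimated correlation). Part of this list may rest on reports that used these samples, so its difference is not independent evidence either. The difference was called for 8 of 22 homologous recombination genes, 6 of 21 CDK inhibitors, 3 of 18 damage sensing genes and 2 of 8 end joining and PARP genes. Adjusted over the list alone these counts were 9, 7, 4 and 2, and the medians of the lists were 0.39, 0.20, 0.07 and 0.19. Their camera adjusted p values were 1.12e-16, 4.79e-06, 0.000614 and 0.00164, with adjusted p = 0.107, 0.128, 0.107 and 0.109 with an estimated correlation. Also called were 3 of 20 replication genes (3 adjusted over the list alone), 1 of 32 G2 and M phase genes (1 adjusted over the list alone, median 0.02), and 2 of 19 oxidative stress genes (2 adjusted over the list alone, median 0.04), OXI1 (3.98 ± 0.52) and UPOX (1.58 ± 0.18). The median of the replication list was -0.03 and its mean 0.61, with no camera call (adjusted p = 0.202).

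Some genes raised in WT were not shown to differ. AT5G07610 had a fitted difference of 6.67 ± 1.32 (adjusted p = 0.170), which rests on 0 of 2 sog1-1 mock and 1 of 2 sog1-1 zeocin arrays well above background and gives no size. WRKY50 and WRKY25 had differences of 2.69 ± 0.51 and 1.16 ± 0.26 (adjusted p = 0.145 and 0.252), and no salicylate gene was called (2 higher adjusted over the list alone). Camera called heat shock higher (median 0.97, adjusted p = 0.000453) and jasmonate lower (-0.53, adjusted p = 0.000284) with no gene called in either, and both lost the call with an estimated correlation (adjusted p = 0.826 and 0.861). Medians of the other lists, salicylate, touch, clock, cell death, iron, copper, shoot and root, were -0.52, -0.07, 0.07, -0.26, -0.20, -0.03, 0.15 and -0.02, without a camera call. For copper the mean was above 0 and the median below 0. By fry, 6 lists moved one way in the difference and 8 passed its mixed form.

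In the difference 5 genes were called lower. AT5G66816 had a difference of -3.05 ± 0.42 and was well above background on 1 of 2 WT mock, 0 of 2 WT zeocin, 0 of 2 sog1-1 mock and 2 of 2 sog1-1 zeocin arrays. AT5G52680 (-2.30 ± 0.30) and AT4G19760 (-2.81 ± 0.38, chosen after its values were seen) were well above background only on the sog1-1 zeocin arrays, at least 2.01-fold and 3.29-fold above sog1-1 mock. AT1G66100, measured on every array, had a difference of -1.32 ± 0.18, and AT1G52820, below background on every sog1-1 array, of -1.25 ± 0.16. All 5 calls ended without either WT mock array or WT zeocin array 2, without the filter on dim probes, and, except that of AT1G66100, with the deposited values. The count of 165 was 96 without a filter on dim probes and 77 to 91 without any 1 array, and the calls of KRP6 and OXI1 ended whichever array was left out. Those of KCS17, SYN2, RNR1 and UPOX ended without most single arrays, and those of KCS17, KRP6, OXI1 and UPOX without the filter on dim probes.

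**Figure D3:**
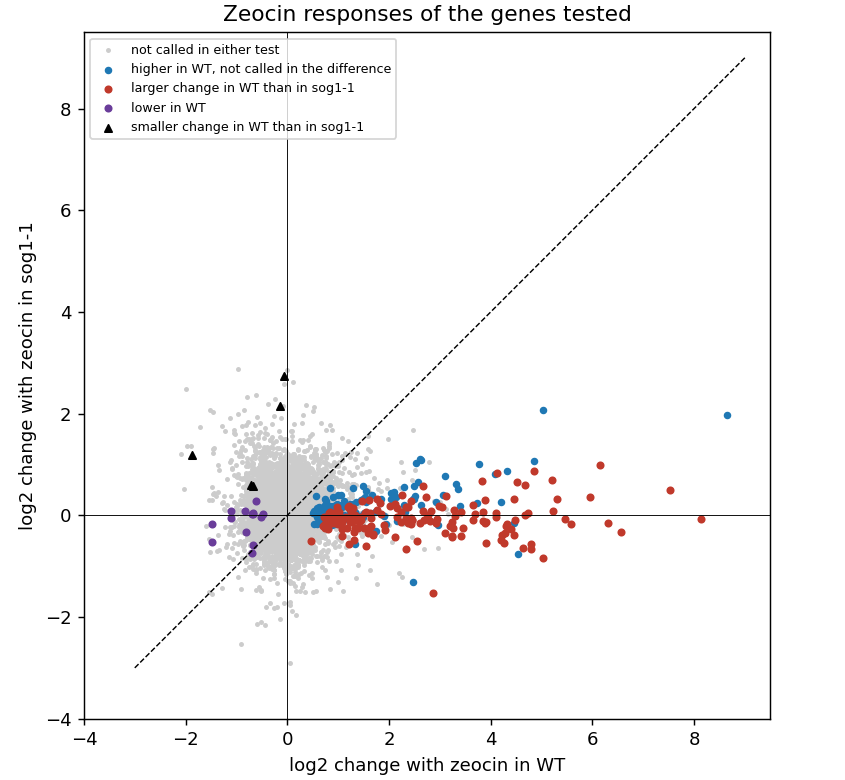
Log2 change with zeocin in sog1-1 (vertical axis) against WT (horizontal axis) for the 22255 genes tested, each a point, with the dashed line marking equal change. The 165 genes with a larger change in WT (red) lie along the horizontal axis, and the 5 with a smaller change (black triangles) lie above it.

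The comparison of sog1-1 with WT without zeocin asked how the genotypes differ at rest. In it 257 genes were higher in sog1-1 and 396 lower, and 444 of these 653 lie on chromosome 1. Of the loci tested on chromosome 1, 7.55% were called, against 0.979 to 1.41% on each other chromosome. The 5 genes with the largest fitted falls were all on chromosome 1, and their order is not known: AT1G22180, AT1G29790, AT1G15670, AT1G35115 and AT1G29800 were well above background on both WT mock arrays and on neither sog1-1 mock array. They were at least 132-fold, 116-fold, 125-fold, 110-fold and 97.5-fold lower (adjusted p between 4.8e-06 and 0.000120). Those with the largest fitted rises included AT1G24370, AT1G24388, AT1G27570 and AT5G33395, below background on both WT mock arrays and at least 507-fold, 86.4-fold, 34.5-fold and 6.78-fold higher. AT2G01422, measured in both genotypes, had a log2 change of 6.22 ± 0.08 (adjusted p = 4.8e-06).

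Few genes of the fixed lists were called at rest. Of the 16 known genes, ANAC044 was higher (0.57 ± 0.09, adjusted p = 0.0367) and PARP2 lower (-0.84 ± 0.15, adjusted p = 0.0458), with the same counts adjusted over the list alone and a list median of -0.25. PARP2 was also the 1 of 8 end joining genes called (median -0.01, 1 lower adjusted over the list alone), and ANAC044 the 1 of 18 damage sensing genes (median -0.04, mean 0.04, 1 higher adjusted over the list alone). Of 32 G2 and M phase genes 2 were lower (3 adjusted over the list alone), the cytokinesis kinesin gene HINKEL (AT1G18370, -0.87 ± 0.13) and CYCB1;2 (AT5G06150, -0.55 ± 0.10), with a list median of -0.17. Of 9 iron deficiency genes, the regulator gene BHLH39 was higher (AT3G56980, 1.14 ± 0.10, adjusted p = 0.00343) and the ferric reductase gene FRO3 lower (AT1G23020, -0.68 ± 0.08, adjusted p = 0.0131), and 6 were higher and 1 lower adjusted over the list alone (median 0.41). HINKEL and FRO3 are chromosome 1 loci. The heat shock list had a median of 1.59 with no gene called (2 higher adjusted over the list alone), and HSP22 had the largest change (2.67 ± 0.60, adjusted p = 0.0915). Its arrays varied, since medians relative to the gene means were -1.12 and -0.29 on WT mock arrays 1 and 2 and 1.29 and 0.01 on sog1-1 mock arrays 1 and 2.

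Camera called 7 lists in this contrast: heat shock (adjusted p = 0.00108), iron deficiency (adjusted p = 0.00773) and jasmonate (median 0.38, adjusted p = 0.0271) higher, and G2 and M phase (adjusted p = 0.000155), DNA replication (median -0.21, adjusted p = 0.00389), known damage response (adjusted p = 0.0267) and shoot markers (median -0.19, adjusted p = 0.0267) lower. All 7 lost the call with an estimated correlation, with adjusted p = 0.842 for jasmonate and adjusted p = 0.7895 for the others, and known damage response also with quantile normalization or the deposited values. By fry, 0 lists moved one way (smallest adjusted p = 0.0590) and 7 passed its mixed form. No gene was called in the lists of homologous recombination, CDK inhibitors, replication, oxidative stress, salicylate, jasmonate, touch, clock, cell death, copper, shoot or root markers. Medians of those not called by camera were -0.13, -0.06, 0.20, 0.29, 0.08, 0.05, -0.12, -0.07 and -0.05 for homologous recombination, CDK inhibitors, oxidative stress, salicylate, touch, clock, cell death, copper and root. Homologous recombination was called lower with signal above background required on all 8 arrays (adjusted p = 0.0305) and with only the mock groups in the fit (adjusted p = 0.0460), and salicylate higher with the deposited values (adjusted p = 0.0472) and without the filter on dim probes (adjusted p = 0.0240). Adjusted over the list alone, 1 clock gene was higher, 1 cell death gene lower, and 1 oxidative stress gene was higher and 1 lower. Genotype and slide row cannot be told apart for any single gene of this contrast, and the excess on chromosome 1 is weighed against the row below. The counts were 93, 118, 90 and 97 higher and 156, 194, 206 and 195 lower without WT mock array 1 or 2 or sog1-1 mock array 1 or 2, and the calls of ANAC044, PARP2, HINKEL, CYCB1;2 and FRO3 ended without either WT mock array or sog1-1 mock array 2, and that of CYCB1;2 without any 1 array or with the deposited values.

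**Figure D4:**
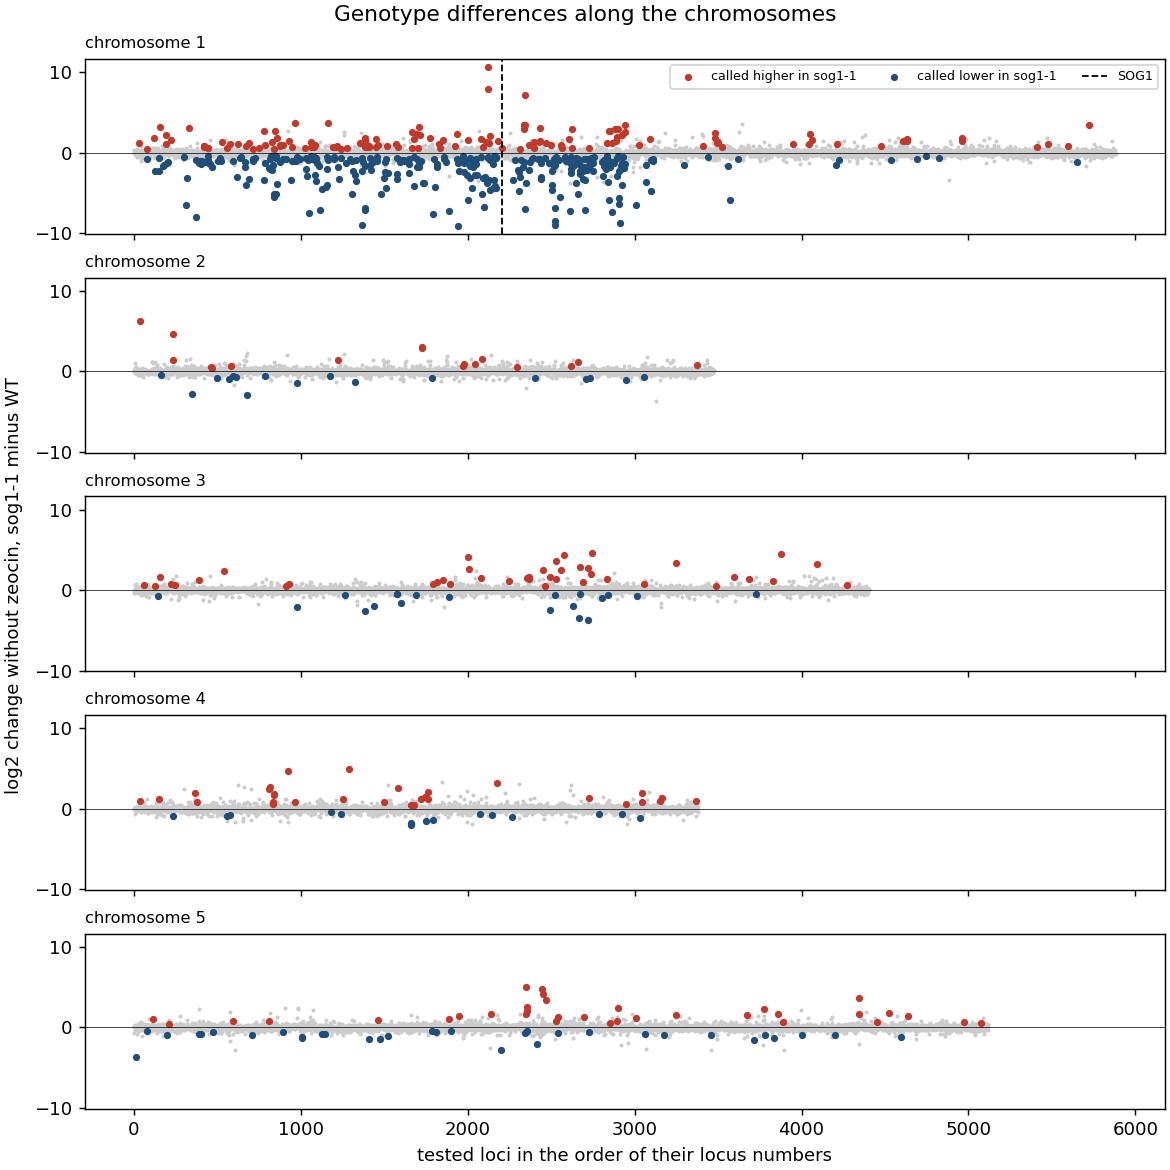
Log2 difference between sog1-1 and WT without zeocin (vertical axis) of the tested loci in the order of their locus numbers (horizontal axis) on each chromosome, with called genes in red (higher in sog1-1) or blue (lower) and SOG1 as a dashed line. Chromosome 1 holds 444 of the 653 called genes.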

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

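The tests of power, of probe binding and of the dose were chosen only after the result was seen. The responses to zeocin differed between the genotypes by the test of the difference itself. That test called 165 genes with a larger change in WT and 5 with a smaller one, 139 of the former being SOG1-dependent raised genes, and camera called 7 gene lists, of which 1, the known damage response genes with a median difference of 4.75, kept the call with an estimated correlation (adjusted p = 0.00757). Part of that list may rest on reports that used these samples, so its difference is not independent evidence. Fitted differences (log2) were 7.02 for SMR7 and 6.45 for TK1A, both measured on every array, and 6.88 for KCS17 and 5.87 for AT4G05380, each well above background on 1 of 2 arrays in every group but WT zeocin. The fitted 8.21 of AT4G25330, below background in every group but WT zeocin, gives no rank, and its rise in WT was at least 60.1-fold. Large differences among list members were those of BRCA1 (5.76), SMR5 (5.14), TSO2 (4.85), SYN2 (4.80), PARP2 (4.69), CYCB1;1 (4.60), COM1 (4.58) and SMR4 (4.45). Smaller ones were those of OXI1 (3.98), PARP1 (3.38), RAD17 (3.36), ANAC044 (3.06), WEE1 (1.79), UPOX (1.58), RNR1 (1.5) and KRP6 (1.47). The 5 genes with the opposite sign were AT1G66100 (-1.32), measured on every array, and AT5G66816, AT4G19760, AT5G52680 and AT1G52820, whose fitted differences (-3.05, -2.81, -2.30 and -1.25) rest on groups below background and give no size.

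The missing response in sog1-1 was weighed against 3 technical explanations. Too little power is argued against for 199 of the 221 genes raised in WT (90.05%), where the 95% interval of the sog1-1 change lay below 50% of the WT change. These genes were chosen by a WT change large relative to the same fitted error, which makes their intervals narrow beside that change. The count therefore says nothing about power for other genes, and 64% of simulated changes of log2 1 were called in sog1-1. Probes that bind sog1-1 transcripts less well around SOG1 are argued against for most of the 139 SOG1-dependent genes, since 37 of them lie on chromosome 1, 1.01 times the share of all tested loci (95% interval 0.737 to 1.32). That share covers all of chromosome 1, while genotype calls crowded into its first 3000 tested loci (13.4% called, against 1.46% on the rest). An excess confined to that part would be diluted. The interval takes genes as independent and does not measure the spread between samples. That zeocin did not reach an effective dose in the sog1-1 plants cannot be told apart from a need for SOG1, because the largest number of genes called for zeocin in sog1-1 was 0 under the 5 ways of computing the values. That count rests on the adjusted threshold, as 1742 genes had an unadjusted p below 0.05 (limma) where chance gives 1113. In its mixed form fry also passed the known damage response genes (adjusted p = 0.00531) and damage sensing (adjusted p = 0.0218). These values leave open whether zeocin acted in sog1-1, since treatment and slide column cannot be told apart. A need for SOG1 in the response therefore stays a hypothesis.

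Probes without a locus name were outside the comparisons of the report. Of the 6219 tested, 46 were higher with zeocin in WT and 0 lower, and 26 of the 6219 had a larger change in WT than in sog1-1 by the test of the difference. The 46 had a median change of 2.88 (2.31 with 17 probes at their bound) in WT and 0.12 in sog1-1, where none was called (limma, with 587 at an unadjusted p below 0.05). Among them, Group5835 was measured on every array and rose by 5.62, and Group5410, below background on both WT mock arrays, had a fitted change of 6.06, which gives no rank.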

How the results depend on the processing

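Every alternative below was chosen before the data were examined. The mean of a gene's probes was planned and not run, because each locus has 1 probe. The cause of a change was not tested unless it is named. A change of sign counted as a reversal only for a result called in at least 1 of the 2 fits compared. Results called in neither fit may have changed direction. Outside the fits that leave out an array, results for named genes stayed on their side of the threshold in 1102 cases. They were no longer called in 120 and newly called in 6, and for lists these numbers were 665, 27 and 10. Without 1 array these numbers were 850, 184 and 6 for genes and 518, 32 and 24 for lists, with 2 reversals. Of 310 genes raised in WT under quantile normalization 299 were among the 303, as were 280 of 327 with the deposited values and 295 of 375 with the replicate block.

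Genes lower in the difference numbered 3 with quantile normalization, 1 with the deposited values, 3 without a filter on dim probes, 1 with signal above background on all 8 arrays, 3 with trend and robust, 28 with the replicate block and 0 at an adjusted p below 0.01. The median sog1-1 response of genes raised in WT was 0.036 with quantile normalization, 0.046 with normexp and quantile, 0.0675 with the deposited values, 0.033 with trend and robust and 0.050 with the block. Without the filter, 22 genes were lower in WT, 96 higher in the difference, 147 higher by genotype, and 1 was SOG1-dependent and lowered. With only the 2 groups compared in the fit, and so fewer residual degrees of freedom, 143 were higher and 1 lower in WT. With the replicate number as a block, 32 were lower in WT, 419 higher by genotype and 2 SOG1-dependent and lowered. The block also brought camera calls for DNA replication, lower in WT (adjusted p = 0.0332), and by genotype for homologous recombination, lower (adjusted p = 0.0350), and salicylate, higher (adjusted p = 0.0195). It ended the camera calls in sog1-1 of CDK inhibitors (adjusted p = 0.0805) and homologous recombination (adjusted p = 0.0556). The replicate numbers do not show that samples were paired, and deviations from group means correlated at 0.12 to 0.52 between groups. List medians were higher on array 1 than on array 2 in all 4 groups for touch, salicylate, jasmonate and oxidative stress. They were lower for shoot markers, G2 and M phase, replication and homologous recombination, the last by little in sog1-1 mock (-0.169 and -0.166). At an adjusted p below 0.01, a stricter threshold, 174 were higher and 0 lower in WT, 73 higher in the difference, 106 higher and 192 lower by genotype, 73 SOG1-dependent and raised, and camera called 4 lists in sog1-1 and 4 by genotype. With log2 1 or more required, 4 were lower in WT, and 160 higher and 241 lower by genotype.

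Leaving out 1 array leaves a group with 1 array, assumed to vary like the others, and fewer degrees of freedom. Ranges were 151 to 241 higher and 2 to 33 lower in WT, 0 to 1 higher and 0 to 1 lower in sog1-1, 77 to 91 higher and 0 to 9 lower in the difference, and 90 to 269 higher and 156 to 383 lower by genotype. SOG1-dependent genes numbered 77 to 88 raised and 0 to 5 lowered, and the median sog1-1 response was -0.037 to 0.055. Camera called 6 to 12 lists in WT, 6 to 9 in sog1-1, 7 to 9 in the difference and 4 to 9 by genotype. The salicylate list in WT reversed to a median of -0.43 without WT zeocin array 1 (adjusted p = 0.511), with 0.64 as the highest median without 1 array, and the jasmonate list in WT to 0.20 without WT zeocin array 2 (adjusted p = 0.00756), with -0.49 as the lowest. Signal over background limits folds for genes off in one group, which are bounds.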

Other observations

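Some genes had changes of like size in both genotypes. AT4G15830 had changes with zeocin of -0.70 ± 0.10 in WT and -0.75 ± 0.10 in sog1-1, with a difference of 0.04 ± 0.14 (adjusted p = 0.935), and AT3G33080 of -0.68 ± 0.11 and -0.58 ± 0.11, with a difference of -0.10 ± 0.15. Both were called in WT and neither in sog1-1. The 32 genes of G2 and M phase had list medians of -0.25 in WT and -0.24 in sog1-1, and the median difference was 0.02 (camera adjusted p = 0.611). Camera called this list lower in both genotypes, and both calls were lost with an estimated correlation (adjusted p = 0.639 and 0.556). As examples of like size, CYCB1;2 had changes of -0.54 ± 0.10 and -0.57 ± 0.10 and HINKEL of -0.38 ± 0.13 and -0.40 ± 0.13, none of them called. Not every member matched, since CYCB1;1 changed by 4.22 in WT and -0.38 in sog1-1. Its difference of 4.60 was the 1 called among the 32. A difference that misses the threshold does not show that the responses were equal. Treatment and slide column cannot be told apart, so like changes in both genotypes need not come from zeocin.

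In the weighing of the genotype contrast, the tests of slide position and of probe binding were chosen only after the result was seen. Of the 653 genes called between sog1-1 and WT without zeocin, 83 lay among the 500 tested loci nearest to SOG1, 5.66 times the share of all tested loci (95% interval 4.56 to 6.90). The row of the slide is argued against as the cause of the excess on chromosome 1, where the share of called genes was 2.57 times that of tested loci (2.43 to 2.71), but for genes on other chromosomes row and genotype cannot be told apart. Among the first 3000 tested loci of chromosome 1, a boundary also chosen after the values were seen, 72.4% of the 402 called genes were lower in sog1-1, against 41.1% of 209 on the other chromosomes, 31.2 percentage points more (two-sided exact Fisher p = 8.73e-14). This p and the intervals above take genes as independent, while all calls rest on 2 arrays per group. They do not measure the spread between samples. A segment of differing sequence around SOG1, with weaker binding to some probes, is a candidate explanation, and true differences in transcript level there stay open. The files hold no sequence that tests it.

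A further hypothesis, also tested only after the values were seen, was that SOG1 holds the genes that depend on it up without added damage. The 139 SOG1-dependent raised genes had a median change between sog1-1 and WT without zeocin of -0.051, with 78 below 0. These genes were chosen by a difference that includes the same mock arrays with the same signs, which pulls this median upward, so the test decides nothing and the hypothesis stays open.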
